A study of Mus musculus with 14 samples.

How the data were processed

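RNA of sorted mouse bone marrow cells was measured on 14 Affymetrix arrays, 1 array per sample. Per the labels, all mice carried floxed Dnmt1 alleles on a C57BL/6 background. Knockout mice also carried the Mx-Cre transgene, which makes the Cre recombinase in response to poly(I)poly(C), and control mice did not. Both genotypes received 7 injections of poly(I)poly(C) at 25 ug/kg, and marrow was taken 4 days after the last injection. Each sample pooled the marrow of 4 to 6 mice of 1 genotype, so every standard error and p-value describes pools of mice and not single mice. Cells with mature lineage markers were depleted, and 3 populations were sorted from the rest: long-term hematopoietic stem cells (LT-HSCs, Kit+ Sca-1+ CD34-), multipotent progenitors (MPPs, Kit+ Sca-1+ CD34+) and myeloid progenitors (Kit+ Sca-1-). LT-HSCs and MPPs had 2 control and 2 knockout arrays each, and myeloid progenitors had 3 and 3. RNA was amplified with the WT-Ovation Pico system and labelled with biotin, per the labels' protocols.

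The deposited values are intensities on a linear scale, 1 per probe set and array, as read from the values themselves. How the authors summarised, background corrected and scaled these intensities is not given in the sources used here. The values run from 0.73 to 19239, and 0.948% of them are exactly 1. The median intensity of an array lay between 41.1 and 49.1, and 31.1% to 37.4% of an array's values were below 16. On the log2 scale the array medians differed by up to 0.26 and the interquartile ranges by up to 0.70. Both exceeded 0.1, the limit set before the data were examined for using the values without further normalization. The values were therefore taken as log2(intensity + 16) and quantile normalized across the 14 arrays. All fold changes are on this scale, which understates the changes of dim genes. For arrays no depth can be stated, and the number of arrays limits the precision.

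The table holds 22690 probe sets, of which 64 are controls. The platform annotation gave 1 gene symbol to 20380 of them, several to 691 and none to 1555. Entrez identifiers of 20351 probe sets were found in the mouse gene table of assembly GRCm38.p6, which changed 0 symbols. The labels name no genome build, so no coordinates are given. A probe set was kept where it exceeded the 40th percentile of its array on at least 2 arrays. Of each gene's probe sets the 1 with the highest mean over all arrays was used, which left 8608 of 12393 genes. Probe sets whose identifiers contain _s_ or _x_ may also bind other transcripts.

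Knockout was compared with control in each population and on average over the 3 populations, where the average is the mean of the 3 differences. The 3 knockout effects were compared with each other as interaction terms, and the control populations were compared as a description of the sorted cells. All comparisons came from 1 limma fit (limma 3.58.1 in R 4.3.3) of 6 group means to the 14 arrays, with a mean-variance trend, 8 residual degrees of freedom and a median of 5.40 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

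Gene lists were fixed before the data were examined, and 25 of them had at least 5 measured members. They cover DNA methylation machinery, germline and early embryo genes, imprinted genes, stem cell genes, lymphoid priming genes, granule genes of myeloid progenitors, cell cycle and stress programmes (DNA replication, mitosis, cell cycle inhibitors, p53 targets, apoptosis regulators, interferon response, immediate early and heat shock genes), adhesion and niche retention, chromatin repressors, ribosomal protein genes and markers of other cells (mature granulocytes, monocytes, dendritic cells and MHC class II, erythroid cells, megakaryocytes, B cells, T and NK cells, mast cells with basophils and eosinophils, endothelial and stromal cells). A list of sex-linked genes had 4 measured members and was not tested. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 100 tests of the 4 knockout comparisons. Camera with an estimated correlation and fry stand beside it. The 75 tests of list interactions were adjusted together, as were the tests of the control populations.

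Same-numbered control and knockout arrays of a population came from littermates, per the labels, which makes 7 pairs. Their deviations from the group means correlated within pairs, with r of 0.46 in LT-HSCs, 0.60 in MPPs and 0.20, 0.54 and 0.61 in myeloid progenitors. With 2 arrays per group both pairs of a population must have the same r. LT-HSCs and MPPs thus give a single value each. The fit had no block, as fixed in advance. A fit with the 7 pairs as blocks, which has 4 residual degrees of freedom, is given where it changes a call or moves a count by more than 1.5 times.

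The genes named were chosen by a rule fixed before the data were examined. It takes Dnmt1 first. For each knockout comparison it takes the 6 largest rises and the 6 largest falls past the threshold that have the same direction in every pair, filled up to 6 with the smallest p-values of that direction, which are given as values only. It adds the 3 members of a gene list with the smallest p, population markers for the controls, and Dnmt3a, Dnmt3b, Uhrf1, Cdkn1a, Cdkn1c, Cxcr4, Mki67 and Xist. Of the markers, Ly6a has no probe set and Mecom did not pass the filter. Genes named outside the rule are marked as chosen after their values were seen.

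The alternatives fixed in advance were the values as deposited, median centring, no filter or one at the 60th percentile, pseudocounts of 1 and 64, the mean over a gene's probe sets, all probe sets singly, both kinds of replicate block, eBayes without a trend or robust, array weights, only the arrays compared, other list tests, and each array left out in turn. After the data were seen, 4 were added: each population without its pair 1, and the 3'/5' ratio of the Gapdh control probe sets, a measure of RNA integrity, as a covariate.

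The scripts were tested on simulated data, with 200 genes changed by known amounts in each of 10 draws of the 14 arrays. Drawing variances from the fitted prior, with 8686 to 8746 genes tested, a change of 2 log2 units was recovered in 81.4% of changed genes in LT-HSCs, 81.6% in MPPs, 93.8% in myeloid progenitors and 99.6% on average. A change of 1 log2 unit was recovered in 18.4%, 16.2%, 38.4% and 79.4%. False calls made up 6.28%, 6.24%, 5.88% and 7.30% of calls, above the nominal level. With the moderated variance of each probe set they made up 7.43%, 7.04%, 7.22% and 9.09%. The model of the variances was changed and the number of draws raised after the earliest simulated results had been seen, so both models are given. Changed genes were drawn only from genes with a brighter mean signal. The shares therefore do not describe genes with a control signal at background, such as Tex19.1. The simulated arrays also had independent noise and no littermate pairs, unlike the real ones. These shares may therefore not hold for the real arrays. A list moved by 1 log2 unit was found in 4 of 4 comparisons, and 1 of 96 other list tests was called with the preset correlation and 0 of 96 with the estimated one.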

Results

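The 14 arrays measured RNA of 3 sorted populations from mice in which Dnmt1, the enzyme that copies DNA methylation onto newly made strands, had been deleted, and from control littermates. LT-HSCs and MPPs had 2 arrays per genotype and myeloid progenitors had 3, in 7 littermate pairs. Array medians lay between 41.1 and 49.1 units of intensity, and arrays of 1 group correlated with r of 0.900 to 0.980. Differences are knockout minus control on the log2(intensity + 16) scale, with the standard error (SE) of the limma fit. The median SE of a gene was 0.35 in LT-HSCs and in MPPs, 0.29 in myeloid progenitors and 0.19 for the average of the 3 populations.

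Dnmt1 itself (Entrez Gene 13433) had a lower signal on the knockout array of all 7 pairs. Its intensity lay between 1328 and 2219 on control arrays and between 745 and 1305 on knockout arrays. The difference was -0.57 ± 0.26 in LT-HSCs (n = 2 per genotype), -0.76 ± 0.26 in MPPs (n = 2) and -0.54 ± 0.21 in myeloid progenitors (n = 3). Leaving out 1 array moved it between -0.82 and -0.33, between -1.06 and -0.46, and between -0.70 and -0.32. The average of -0.63 ± 0.14 missed the threshold (adjusted p = 0.193), and with the pairs as blocks it passed (adjusted p = 0.0371, with 0.0245 to 0.522 over the alternatives). Another Dnmt1 probe set gave -0.99 in LT-HSCs, -1.09 in MPPs and -1.07 in myeloid progenitors. The labels do not say which part of the gene was deleted, so the probe sets may lie outside it and the signal checks the labels only in part.

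Other genes of the DNA methylation machinery had small differences that did not pass the test. On average Dnmt3a and Dnmt3b, the enzymes that set new methylation, were at -0.21 ± 0.16 and 0.21 ± 0.19. Leaving out 1 array moved them between -0.36 and -0.06 and between 0.05 and 0.38. Uhrf1, which brings Dnmt1 to replicated DNA, was at 0.13 ± 0.17, and at -0.04 without LT-HSC control array 2. The list of 14 genes had a median of -0.01 (camera adjusted p = 0.495). By limma 0 of its members passed over all genes and 1 was below an unadjusted p of 0.05. Adjusted over the list alone, 1 of them, Dnmt1, fell.

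The control populations were compared to describe what had been sorted. Cd34, which the sort itself separates, was lower in LT-HSCs than in MPPs by -4.17 ± 0.60 (adjusted p = 0.00366, n = 2 per group). The granule protein genes Mpo and Elane were lower in LT-HSCs, at -4.31 ± 0.50 (adjusted p = 0.00113) and -3.78 ± 0.66 (adjusted p = 0.0125). Il7r, the receptor of lymphoid progenitors, was higher in LT-HSCs by 3.47 ± 0.69 (adjusted p = 0.0206). The other markers did not pass: Flt3 was at -2.45, Procr at -1.72, Hlf at -1.58, Gata1 at 1.65 (2.57 without LT-HSC control array 1), Irf8 at -1.10, Kit at -0.88 and Meis1 at -0.38. The stem cell genes Procr, Hlf and Meis1 were thus not higher in the LT-HSC arrays. Leaving out 1 array moved Hlf between -2.29 and -0.87, Irf8 between -2.00 and -0.19 and Kit between -1.36 and -0.41. In all, 98 genes were higher and 102 lower in LT-HSCs, and the count of 200 became 78 and 422 without LT-HSC control array 1 or 2 and 85 and 97 without MPP control array 1 or 2. Elane without MPP control array 2 was at -2.50 (adjusted p = 0.0555), Il7r was at 2.58 (adjusted p = 0.167) without LT-HSC control array 1 and at 2.76 (adjusted p = 0.128) without MPP control array 2, and Meis1 was at 0.10 without LT-HSC control array 1.

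B cell markers were a feature of the control LT-HSC arrays, with a median 2.59 higher than in MPPs (camera adjusted p = 7.04e-14). With an estimated correlation the adjusted p was 0.174. Granule genes had a median of -2.28 (adjusted p = 7.61e-14, and adjusted p = 0.125 with an estimated correlation). Smaller shifts past the preset threshold were those of erythroid markers at 1.06, mature granulocyte markers at -0.98, monocyte markers at -0.93, mast cell markers at -0.90, mitosis genes at 0.56, DNA methylation machinery at 0.52 and cell cycle inhibitors at 0.46. With an estimated correlation their adjusted p lay between 0.174 and 0.524. Stem cell genes had a median of -0.24 (camera adjusted p = 0.130, and 0.688 with an estimated correlation). The arrays therefore did not show the sorted LT-HSCs to be richer in stem cell genes than MPPs, which limits what the LT-HSC results say about stem cells.

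Between control myeloid progenitors and control MPPs 7 genes differed, 5 higher and 2 lower in myeloid progenitors. They included the erythroid genes Car1, at 3.71 (adjusted p = 0.00768), and Ermap, at 3.38, and the MHC class II chain gene Cd74, at -2.60 (adjusted p = 0.0328), chosen here after their values were seen. None of the 11 markers fixed in advance passed: Flt3 was at -2.88, Hlf at -2.84, Procr at -2.67, Elane at 2.47, Irf8 at 1.49, Cd34 at -1.30, Meis1 at -1.10, Gata1 at 1.06, Kit at -0.63, Mpo at 0.37 and Il7r at -0.34. Lists that passed were MHC class II markers at -1.30, erythroid markers at 0.99, lymphoid priming genes at -0.86, mast cell markers at 0.84, granule genes at 0.72, mature granulocyte markers at 0.72, stem cell genes at -0.63, the interferon response at -0.51, megakaryocyte markers at -0.45, T and NK markers at -0.28 and replication genes at 0.20. With an estimated correlation their adjusted p lay between 0.125 and 0.721. The count of 7 became 0 and 188 without MPP control array 1 or 2, and 2 and 0 without myeloid progenitor control array 2 or 3. Without MPP control array 2 Elane was at 3.75 (adjusted p = 0.00426), Hlf at -3.50 (adjusted p = 0.0180) and Procr at -3.43 (adjusted p = 0.0348), and Il7r turned to 0.37 without MPP control array 1.

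The main question was which genes change when Dnmt1 is lost. Averaged over the 3 populations, 20 genes rose in knockout cells, led by Tex19.1, Trap1a, Tex19.2 and Rhox5. Tex19.1 (Entrez Gene 73679), a gene of germ cells and pluripotent cells, rose by 5.03 ± 0.33 (adjusted p = 7.6e-06, n = 7 arrays per genotype). Its intensity lay between 3.08 and 8.04 units on control arrays and between 193 and 1023 on knockout arrays. Trap1a (Entrez Gene 22037), an X-linked tumour rejection antigen of testis and placenta, rose by 4.42 ± 0.41 (adjusted p = 1.3e-04). The related Tex19.2 (Entrez Gene 70956) rose by 4.06 ± 0.34 and the X-linked homeobox gene Rhox5 (Entrez Gene 18617) by 3.54 ± 0.30, both with an adjusted p of 4.34e-05. Rpl39l, a ribosomal protein gene used in testis, rose by 3.43 ± 0.54 (adjusted p = 0.0140), and Gm9222 by 3.05 ± 0.31 (adjusted p = 3.05e-04). The only probe set of Gm9222 is of the _x_ kind, which may also bind other transcripts, here and in the single populations. The control signal of Tex19.1, Trap1a, Tex19.2 and Rhox5 was at background, so the size of their rises, and their rank, is set by the pseudocount: Tex19.1 was at 6.89 with a pseudocount of 1 and 3.42 with 64, and the 4 genes passed with both. Rpl39l and Dazl, at 5.03 to 9.56 and 1.39 to 7.56 units on control arrays, have the same limit on the size of their rises.

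All 20 genes were higher on the knockout array in 7 of 7 pairs. The other 14 rose by 0.96 to 2.80. Among them were Dazl, an RNA-binding protein gene of germ cells, at 2.80, the meiotic recombination gene Mnd1 at 2.59 and the testis dipeptidase gene Dpep3 at 2.12. Ipp, named for transcripts that start in an IAP retroelement, rose by 2.02, the slow muscle troponin gene Tnnt1 by 2.20 and the circadian gene Noct by 2.29, all 3 chosen after their values were seen.

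**Figure D1:**
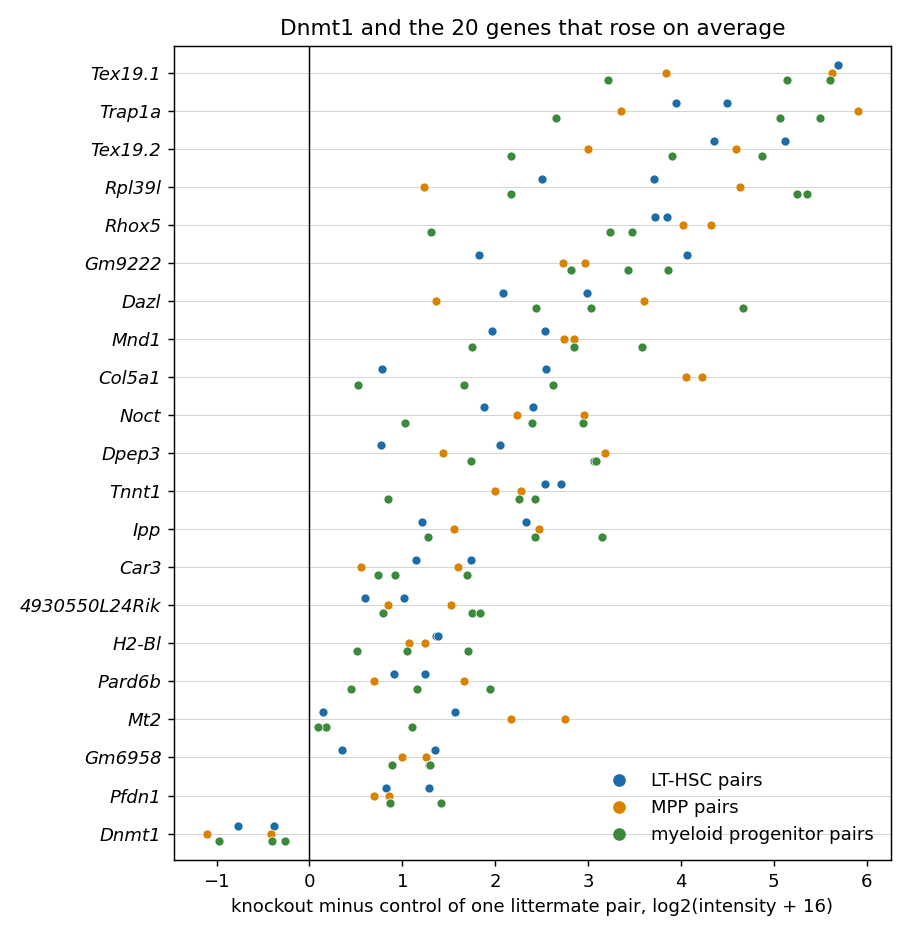
Difference between the knockout and the control array of each littermate pair, log2(intensity + 16), for Dnmt1 and the 20 genes that rose on average over the 3 populations. Each point is 1 of the 7 pairs, coloured by population, and all points of the 20 genes lie above 0 and all points of Dnmt1 below 0.

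By limma 0 genes fell on average, with 246 of 8608 lower at an unadjusted p under 0.05. The falls with the smallest p besides Dnmt1, given as values, were Cd93, a receptor on early progenitors, at -1.02, Ttc4 at -0.92, Hnmt, which inactivates histamine, at -0.81, C87436 at -0.77 and Rasa4 at -0.71. With the pairs as blocks 55 genes rose and 14 fell, which makes 69, and the 20 were all among them. Blocked adjusted p was then 0.0178 for Ttc4 (0.0178 to 0.659 over the alternatives), 0.0286 for Cd93 (0.0282 to 0.918) and 0.0441 for Rasa4 (0.0441 to 0.659). The count of 20 became 59 and 42 without LT-HSC control or knockout array 2, 13 without LT-HSC knockout array 1 and 12 without MPP control array 1. Rpl39l missed the threshold without LT-HSC knockout array 1 (adjusted p = 0.0578) and without MPP control array 1 (0.0628) or 2 (0.0572).

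Germline and early embryo genes rose as a list on average, with a median of 0.83 over 15 measured genes (camera adjusted p = 3.45e-14). With an estimated correlation the adjusted p was 0.135, and 0.627 with the pairs also as blocks. The median was 0.54 without MPP knockout array 2. Over all genes 3 of them rose, Rhox5, Dazl and Dpep3, and adjusted over the list alone 8 rose. The filter bears on this list, since of 28 members with a probe set 15 passed it. Rhox5 and Dazl, at no more than 7.39 and 7.56 units on control arrays, passed only through knockout arrays. The filter thus favours members that rose, here and in each population, and the list p-values do not allow for this. Imprinted genes had a smaller median of 0.15 over 17 genes (adjusted p = 0.0157, and adjusted p = 0.772 with an estimated correlation). Its members with the smallest p were Cdkn1c at 0.49, Plagl1 at 0.97 and Peg12 at 0.53, and by limma 0 passed over all genes, 0 adjusted over the list alone and 6 were higher at an unadjusted p under 0.05. The imprinted list with pairs as blocks missed the threshold (adjusted p = 0.0687, with 0.00120 to 0.804 over the alternatives). It also did so without LT-HSC control array 1 (0.0673) or knockout array 1 (0.140) and without MPP control array 2 (0.186) or knockout array 1 (median 0.25, 0.0825). Its median was 0.07 without LT-HSC knockout array 1 and 0.24 without LT-HSC knockout array 2.

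**Figure D2:**
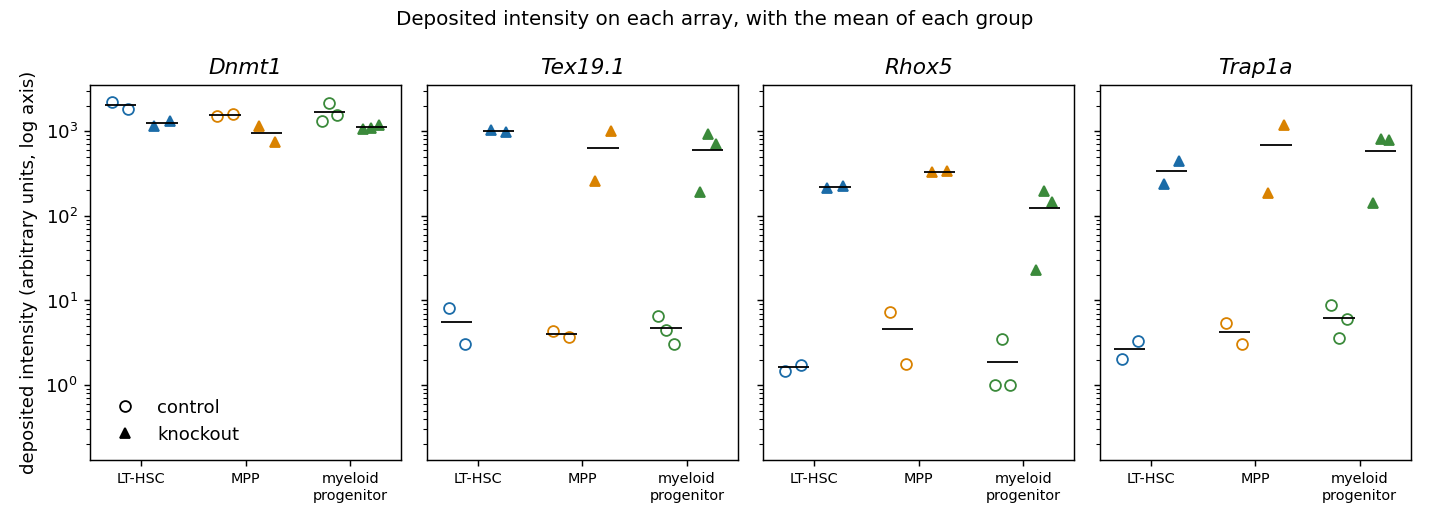
Deposited intensity of Dnmt1, Tex19.1, Rhox5 and Trap1a on each of the 14 arrays, on a log axis, with a bar at the mean of each group. The ranges of control and knockout arrays do not overlap for any of the 4 genes: Dnmt1 lies at 1328 to 2219 and 745 to 1305, and Tex19.1 at 3.08 to 8.04 and 193 to 1023.

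In LT-HSCs 4 genes rose and 2 fell. Tex19.1 rose by 5.69 ± 0.61 (adjusted p = 0.00288, n = 2 per genotype), Tex19.2 by 4.74 ± 0.62 (adjusted p = 0.00907) and Rhox5 by 3.78 ± 0.54 (adjusted p = 0.0177). Rhoc, a small GTPase of the cytoskeleton, rose by 3.41 ± 0.41 (adjusted p = 0.00584), from 3.98 and 2.00 units of intensity to 292.93 and 108.53. The probe set used is of the _s_ kind, which may also bind other transcripts. The other probe set of Rhoc, at -0.10, had almost no signal on any array, knockout arrays included. A rise of Rhoc itself is therefore not established. The control signal of Rhoc was at background, so the pseudocount sets the size of its rise. Lef1, a transcription factor of Wnt signalling and lymphocyte development, fell by 2.06 on the log2 scale (adjusted p = 0.0319), and Ankrd33b fell by 1.90 (adjusted p = 0.0319). All 6 had the same direction in both pairs. Control LT-HSCs also carried more B cell marker signal than control MPPs (median 2.59 higher). The fall of Lef1 may therefore lie in lymphoid cells among the sorted cells. The B cell list itself did not pass in knockout LT-HSCs, and the source of the Lef1 signal was not tested.

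Trap1a, at 4.22 ± 0.76 (adjusted p = 0.0991), and Slpi, a protease inhibitor of leukocytes, at 3.31 ± 0.60 (adjusted p = 0.103), missed the threshold in LT-HSCs, as did Hdac6 at -1.67, Gde1 at -1.43, Ckap2 at -1.39 and Sharpin at -1.34. The blocked fit had 13 genes that rose and 7 that fell, which makes 20. Blocked adjusted p was then 0.0372 for Trap1a (0.00710 to 1.00 over the alternatives), 0.0157 for Slpi (0.00537 to 1.00), 0.0341 for Sharpin (0.0341 to 1.00) and 0.0454 for Gde1 (0.0410 to 1.00). The count of 6 became 2 and 77 without knockout array 1 or 2, 35 without control array 2, 5 without control array 1, and 0 without both arrays of pair 1, an alternative chosen after seeing the data. Lef1, Ankrd33b, Rhox5 and Tex19.2 missed the threshold without control array 1 (adjusted p = 0.296, 0.222, 0.151 and 0.0878) and without knockout array 1 (0.176, 0.322, 0.176 and 0.165), and Ankrd33b also without control array 2 (0.0516). Without knockout array 2 Slpi was at 4.32 (adjusted p = 0.00712) and Hdac6 at -2.04 (adjusted p = 0.0224), and without control array 2 Hdac6 was at -2.00 (adjusted p = 0.0407).

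T and NK cell markers rose as a list in knockout LT-HSCs, with a median of 0.66 over 16 genes and 14 of them positive (camera adjusted p = 1.37e-06). It passed with an estimated correlation (adjusted p = 0.0282), but not once the pairs were also used as blocks (adjusted p = 0.265). Il2rb, a chain of the IL-2 and IL-15 receptors, was at 1.49, Thy1 at 1.54 and Eomes, a transcription factor of NK cells, at 1.06. Over all genes 0 members passed by limma, 5 were higher at an unadjusted p under 0.05, and adjusted over the list alone 5 rose. The pairs gave medians of 0.64 and 0.72. On average over the 3 populations the list also rose, with a median of 0.35 (adjusted p = 4.05e-05, adjusted p = 0.0353 with an estimated correlation, and adjusted p = 0.265 with the pairs also as blocks), 0 of 16 members past the threshold, 5 higher at an unadjusted p under 0.05 and 3 adjusted over the list alone. Swaps of the genotypes within pairs gave the average list an exact adjusted p of 0.195.

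Mitosis genes fell in knockout LT-HSCs, with a median of -0.26 and 24 of 26 negative (adjusted p = 6.97e-04, and adjusted p = 0.772 with an estimated correlation). Ttk was at -1.35, Cenpa at -0.69 and Ccna2 at -0.62. Lymphoid priming genes fell with a median of -0.32 (adjusted p = 0.0209, and adjusted p = 0.803 with an estimated correlation), among them Il7r at -1.62, Il12a at -1.54 and Rag2 at -1.42, where control LT-HSCs also carried more B cell marker signal than control MPPs (2.59). B cell markers themselves had a median of -0.34 in knockout LT-HSCs, with 11 of 16 negative and pairs at -0.40 and -0.19, and did not pass (adjusted p = 0.351). Germline genes rose with a median of 0.54 (adjusted p = 6.04e-05, and adjusted p = 0.745 with an estimated correlation), with Dazl at 2.54 and Piwil2 at 1.23. Erythroid markers rose with a median of 0.37 (adjusted p = 0.00531, and adjusted p = 0.772 with an estimated correlation), among them Slc4a1 at 1.34, Alas2 at 1.08 and Epor at 1.04, but the pairs were at 0.94 and -0.08. Over all genes 1 germline gene rose and, by limma, 0 genes of the other 3 lists passed, with 4 mitosis genes and 4 lymphoid genes lower and 2 erythroid genes higher at an unadjusted p under 0.05. Adjusted over the list alone, 1 mitosis gene fell, 0 lymphoid genes passed, and 2 germline genes and 1 erythroid gene rose.

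Erythroid, mitosis and lymphoid priming genes were less stable in LT-HSCs than T and NK markers when single arrays were left out. Both arrays of pair 1 had a Gapdh 3'/5' ratio, a measure of RNA integrity, of 5.44 and 5.15, against 3.07 and 2.46 in pair 2. The Actb 3'/5' ratio ran the other way, at 0.81 and 0.75 against 0.97 and 1.09, so the 2 controls did not rank the arrays alike. Germline genes were at 0.14 without knockout array 1 and 0.95 without knockout array 2. Without control array 2 the medians of erythroid, mitosis and lymphoid genes were 1.08, -0.60 and -1.01, and that of mitosis genes was -0.52 without knockout array 1. Without control array 1 the erythroid median was -0.18, that of mitosis genes -0.02 (adjusted p = 0.728) and that of lymphoid genes -0.42 (adjusted p = 0.272). Without knockout array 1 the lymphoid list had an adjusted p of 0.172 and the erythroid list of 0.0767. Without knockout array 2 the mitosis median was -0.05 (adjusted p = 0.408) and the lymphoid list had an adjusted p of 0.0801. Mature granulocyte markers, at 0.49 (adjusted p = 0.132), passed with the pairs as blocks (adjusted p = 0.0355), although the pairs were at -0.52 and 1.68 and the adjusted p was 0.663 with blocks and an estimated correlation.

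In MPPs 6 genes rose. Tex19.1 rose by 4.73 ± 0.61 (adjusted p = 0.0122, n = 2 per genotype), Rhox5 by 4.17 ± 0.54 (adjusted p = 0.0122), and Trap1a and Tex19.2 by 4.63 ± 0.76 and 3.80 ± 0.62 (adjusted p = 0.0469 for both). The collagen gene Col5a1 rose by 4.14 ± 0.66 (adjusted p = 0.0469), while its other probe sets were at 0.53 and 2.03. Mt2, a metallothionein that binds zinc and copper, rose by 2.46 ± 0.37 (adjusted p = 0.0354). All 6 were higher in both pairs.

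By limma 0 genes fell in MPPs, with 107 lower at an unadjusted p under 0.05. In both directions 229 genes were below it where 430.4 are expected by chance, so 0 falls do not show that no gene fell. Pcp4l1 was at -1.42, the transcription factor gene Sox4 at -1.16, Trim26 at -1.16, Camk2a at -1.09, Sgpl1 at -1.01 and B3gnt5 at -0.93. Pairs as blocks gave 12 genes that rose and 1 that fell, which makes 13. Without control array 1 or 2 the count was 0 and 0, without knockout array 1 or 2 it was 2 and 2, and without both arrays of pair 1 it was 0. The adjusted p of the 6 genes lay between 0.260 and 0.762 without control array 1, between 0.147 and 0.173 without control array 2 and between 0.125 and 0.438 without knockout array 2. Without knockout array 1 Tex19.2, Rhox5, Col5a1 and Mt2 missed the threshold (0.0503, 0.108, 0.139 and 0.210).

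Erythroid markers rose in knockout MPPs, with a median of 0.69 and 17 of 18 positive (camera adjusted p = 3.45e-14). With an estimated correlation the adjusted p was 0.135. Car1, an early carbonic anhydrase of red cell precursors, was at 2.46, Ermap at 2.19 and Epor, the erythropoietin receptor, at 2.06. Over all genes 0 passed by limma, 7 were higher at an unadjusted p under 0.05, and adjusted over the list alone 5 rose. The pairs were at 0.71 and 0.83, and on average over the 3 populations the list rose with a median of 0.47 (adjusted p = 6.73e-11, and adjusted p = 0.204 with an estimated correlation), with 0 past the threshold, 7 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone. The average median was 0.31 without LT-HSC control array 1. Slc4a1, the band 3 anion exchanger, was at 0.85 on average, Epor at 1.12 and Gata1 at 1.00.

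Mast cell, basophil and eosinophil markers also rose in knockout MPPs, with a median of 0.95 and 12 of 12 positive (adjusted p = 3.43e-05, and adjusted p = 0.620 with an estimated correlation). The histidine decarboxylase gene Hdc was at 1.61 and the protease genes Cma1 and Cpa3 at 1.26 and 0.80. Single arrays moved the median, to 0.46 without control array 1, 1.53 without knockout array 1 and 0.24 without knockout array 2. Lymphoid priming genes fell with a median of -0.50 (adjusted p = 0.00531, and adjusted p = 0.772 with an estimated correlation), among them Ighm at -1.82, Flt3 at -1.48 and Satb1 at -0.91. By limma 0 members of either list passed over all genes or adjusted over the list alone, with 1 mast cell gene higher and 1 lymphoid gene lower at an unadjusted p under 0.05. On average over the 3 populations the mast cell list was at 0.28 (adjusted p = 0.0314, and adjusted p = 0.772 with an estimated correlation) and the lymphoid list at -0.53 (adjusted p = 6.97e-04, and adjusted p = 0.772 with an estimated correlation), with Il7r at -0.89, Il12a at -0.72 and Satb1 at -0.57. The average mast cell call ended without LT-HSC control array 2 (0.154) or knockout array 1 (median 0.13, 0.242), MPP control array 1 (0.132) or knockout array 2 (median 0.11, 0.113) and myeloid progenitor control array 1 (0.0622) or 2 (0.158) or knockout array 3 (median 0.18, 0.231). Without MPP knockout array 2 the lymphoid median turned to 0.14 in MPPs and was -0.20 on average (adjusted p = 0.204), and without MPP control array 1 it was -0.14 in MPPs (adjusted p = 0.404) and -0.32 on average. It was -1.09 in MPPs without control array 2 and -1.37 without knockout array 1, and the average mast cell median was 0.46 without MPP knockout array 1.

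Germline genes rose in MPPs with a median of 0.61 (adjusted p = 2.28e-06, and adjusted p = 0.620 with an estimated correlation), with Dazl at 2.48 and Dpep3 at 2.31, 1 gene past the threshold over all genes and 3 adjusted over the list alone. As on average, the filter favours germline genes that rose. Mitosis genes rose with a median of 0.22 (adjusted p = 0.00216), DNA replication genes with 0.15 (adjusted p = 0.00805) and imprinted genes with 0.39 (adjusted p = 0.0431), all 3 with an adjusted p of 0.772 with an estimated correlation. Examples are Aurkb at 0.74, Cdc20 at 0.46 and Ube2c at 0.44 for mitosis, E2f1 at 0.53, Cdc45 at 0.48 and Cdc6 at 0.40 for replication, and Grb10 at 0.76, Cdkn1c at 0.70 and Airn at 0.62 for imprinting. By limma 0 members of these 3 lists passed over all genes or adjusted over the list alone, with 1 imprinted gene and 0 of the others higher at an unadjusted p under 0.05. The imprinted list missed the threshold with the pairs as blocks (adjusted p = 0.0879, with 5.15e-04 to 0.939 over the alternatives), and its median was -0.06 with the filter at the 60th percentile (adjusted p = 0.587). Without MPP control array 1 the mitosis median was -0.06 and that of replication genes 0.04 (adjusted p = 0.992). Without knockout array 2 the medians of germline, mitosis and replication genes were 0.06 (adjusted p = 0.0656), 0.20 (adjusted p = 0.0532) and 0.05 (adjusted p = 0.244), and the imprinted median was 0.21 and 0.06 without control array 2 or knockout array 1 (adjusted p = 0.739 and 0.392). Without control array 2 the mitosis and replication medians were 0.54 and 0.33, and the germline median was 0.95 without knockout array 1.

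**Figure D3:**
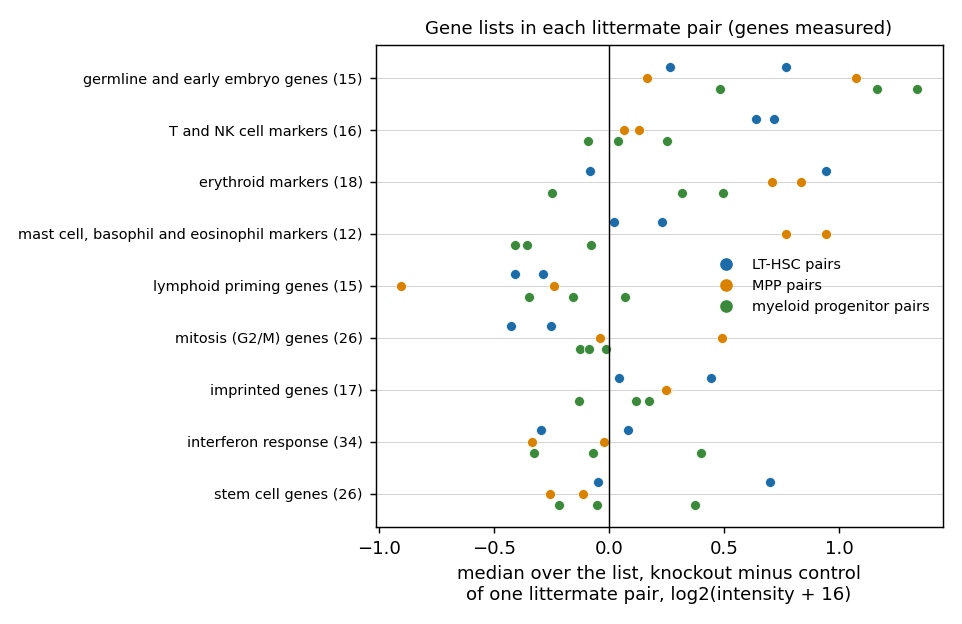
Median difference between the knockout and the control array of each littermate pair, log2(intensity + 16), for 9 of the 25 gene lists, with the number of measured genes in brackets. Each point is 1 pair: the erythroid markers of the MPP pairs lie at 0.71 and 0.83, those of the LT-HSC pairs at 0.94 and -0.08, and the MPP points of imprinted genes coincide at 0.25.

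In myeloid progenitors 8 genes rose. Tex19.1 rose by 4.66 ± 0.50 (adjusted p = 0.00282, n = 3 per genotype), Trap1a by 4.41 ± 0.62 and Tex19.2 by 3.65 ± 0.51 (adjusted p = 0.0142 for both), and Rhox5 by 2.67 ± 0.44 (adjusted p = 0.0397). Dazl rose by 3.38 ± 0.51 (adjusted p = 0.0215), Gm9222 by 3.37 ± 0.47 (adjusted p = 0.0142), Mnd1 by 2.73 ± 0.40 (adjusted p = 0.0197) and Dpep3 by 2.63 ± 0.42 (adjusted p = 0.0335). All 8 were higher in 3 of 3 pairs.

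By limma 0 genes fell in myeloid progenitors, with 16 lower at an unadjusted p under 0.05. In both directions 88 genes were below it where 430.4 are expected by chance. The p-values of the unblocked fit were thus conservative, and 0 falls do not show that no gene fell. The smallest p belonged to Tmem106c at -1.40, Tgfbi at -1.32, the transcription factor gene Klf4 at -1.19, Gspt2 at -0.77, Dnmt1 at -0.54 and Cmtm7 at -0.42. With the pairs as blocks 13 genes rose and 0 fell. The count of 8 became 1, which was Tex19.1, without control array 1, 2 or 3 or knockout array 2 or 3, and 13 without knockout array 1. Trap1a, Tex19.2, Dazl, Gm9222 and Mnd1 had an adjusted p between 0.0744 and 0.157 in those 5 fits with 1 call. The Gapdh 3'/5' ratio was 5.27 on control array 1 and 2.33 on knockout array 1 of the same pair.

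Germline genes rose as a list in myeloid progenitors, with a median of 1.00 and 13 of 15 positive (camera adjusted p = 3.67e-32), and passed with an estimated correlation (adjusted p = 0.0282). It did not pass with fry (adjusted p = 0.112), nor with an estimated correlation and the pairs as blocks (adjusted p = 0.265). Over all genes 3 of them rose and adjusted over the list alone 8 rose. The filter favours germline genes that rose here too, so the list p-values are tilted towards a rise. Immediate early and heat shock genes fell with a median of -0.64 (adjusted p = 0.0157, and adjusted p = 0.803 with an estimated correlation), among them Klf4 at -1.19, Klf2 at -0.81 and Zfp36 at -0.71, although the pairs were at -0.76, -1.06 and 0.03. Erythroid markers rose with a median of 0.19 (adjusted p = 0.0110, and adjusted p = 0.772 with an estimated correlation), with Slc4a1 at 0.48, Gata1 at 0.38 and Hemgn at 0.35, although the pairs were at 0.32, 0.49 and -0.25. The p53 targets rose with a median of 0.08 (adjusted p = 0.0191, and adjusted p = 0.745 with an estimated correlation), with Perp at 1.55, Cdkn1a at 0.76 and Phlda3 at 0.49. By limma 0 members of these last 3 lists passed over all genes or adjusted over the list alone, with 1 immediate early gene lower, 0 erythroid genes and 2 p53 targets higher at an unadjusted p under 0.05.

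Single arrays ended some of these calls. Immediate early genes were at -0.15 without control array 1 (adjusted p = 0.823), -0.24 without control array 2 (adjusted p = 0.127) and -0.32 without knockout array 3 (adjusted p = 0.327). Erythroid markers were at 0.14 without control array 1 (adjusted p = 0.376) and 0.06 without knockout array 2 (adjusted p = 0.418). The p53 targets had an adjusted p of 0.171 and 0.0561 without control array 2 or 3 and of 0.0925 without knockout array 2. Immediate early genes were at -1.35 without control array 3 and -1.01 without knockout array 1, erythroid markers at 0.37 without knockout array 3, and p53 targets at 0.14 and 0.05 without control array 1 or 2 and 0.14 without control array 3. With the pairs as blocks mature granulocyte markers, at -0.20 (adjusted p = 0.0564), and mast cell markers, at -0.21 (adjusted p = 0.245), passed in myeloid progenitors (adjusted p = 0.00858 and 0.0243), and so did immediate early genes in MPPs, at -0.65 (0.0744 without and 8.22e-04 with blocks). With blocks and an estimated correlation none of the 3 passed (adjusted p = 0.663, 0.627 and 0.659), and the MPP pairs of immediate early genes were at -1.17 and 0.05.

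The knockout effect was compared between populations to ask whether they respond differently. Tex19.1, Tex19.2 and Rhox5 rose in all 3, 4 genes passed in 2 or more, and 13 passed in any. The 8 genes that rose in myeloid progenitors were all positive in LT-HSCs, with a median of 3.36, and in MPPs, with a median of 3.32. The fry adjusted p was 5.39e-04 for both. The filter, the normalization and the variances of the fit came from the arrays of all populations together. Whether the populations were sorted from the same pools of mice was not established here. These values are therefore not an independent replication. Of the 4 genes that rose in LT-HSCs 4 were positive in MPPs and 3 in myeloid progenitors, where Rhoc was at -0.08, and the 6 of MPPs were all positive in both others. Across all 8608 genes, which are not independent replicates, the differences correlated with r of 0.26 between LT-HSCs and MPPs, 0.30 between LT-HSCs and myeloid progenitors and 0.45 between MPPs and myeloid progenitors.

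By limma 0 genes differed in their knockout effect between myeloid progenitors and LT-HSCs, MPPs and LT-HSCs, or myeloid progenitors and MPPs, with 229, 260 and 42 genes below an unadjusted p of 0.05 where 430.4 are expected by chance. With fewer such genes than chance gives, the p-values were conservative, and 0 calls do not show that the populations respond alike. The counts past the threshold were also 0 with the pairs as blocks. Without LT-HSC knockout array 2 they became 1 and 4 for the comparisons with LT-HSCs, and without MPP knockout array 2 they became 1 for each comparison with MPPs.

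The p53 targets rose on average with a median of 0.13 (adjusted p = 0.0474, and adjusted p = 0.772 with an estimated correlation), with Perp, a membrane protein induced by p53, at 1.48, Phlda3 at 0.62 and Cdkn1a, which encodes the cell cycle inhibitor p21, at 0.54 and higher in 7 of 7 pairs. By limma 0 of 20 passed over all genes, 4 were higher at an unadjusted p under 0.05 and adjusted over the list alone 2 rose. With the pairs as blocks the list missed the threshold (adjusted p = 0.0747, with 0.00609 to 0.804 over the alternatives), as it did without LT-HSC control array 1 (0.0503) or 2 (0.154), LT-HSC knockout array 1 (-0.01, 0.501), MPP control array 2 (0.192), MPP knockout array 2 (0.0547), myeloid progenitor control array 2 (0.0861) and knockout array 2 (0.0630). Its median was 0.25 without LT-HSC knockout array 2 and 0.06 without MPP knockout array 1.

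DNA replication genes rose on average with a median of 0.09 (adjusted p = 0.0191, and adjusted p = 0.772 with an estimated correlation), with Cdc45 at 0.40, Cdc6 at 0.29 and Mcm3 at 0.16, 0 past the threshold by limma over all genes or adjusted over the list alone, and 2 higher at an unadjusted p under 0.05. They missed the threshold without LT-HSC control array 2 (median 0.05, 0.291) or knockout array 2 (0.178) and without MPP control array 1 (median 0.02, 0.333) or knockout array 2 (0.0945), and their median was 0.14 without MPP control array 2 and 0.06 without myeloid progenitor knockout array 1. Of the other genes fixed in advance, Cdkn1c was at 0.49, the chemokine receptor gene Cxcr4 at -0.27, the proliferation marker Mki67 at -0.03 and Xist at 0.02 on average, and none passed. Single arrays left out moved Mki67 between -0.14 and 0.09 and Xist between -0.12 and 0.16.

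Many programmes showed no shift that passed on average. Stem cell genes had a median of 0.01 (camera adjusted p = 0.757), granule genes -0.01 with a mean of 0.02 (adjusted p = 0.831), mature granulocyte markers 0.04 with a mean of -0.06 (adjusted p = 0.899), monocyte and macrophage markers 0.09 (adjusted p = 0.503), dendritic cell and MHC class II markers 0.22 (adjusted p = 0.0908) and megakaryocyte markers 0.02 (adjusted p = 0.623). B cell markers were at -0.01 (adjusted p = 0.759) and endothelial and stromal markers at -0.05 (adjusted p = 0.874). Mitosis genes were at -0.04 (adjusted p = 0.456), cell cycle inhibitors at -0.18 (adjusted p = 0.369), apoptosis regulators at 0.02 (adjusted p = 0.939) and immediate early and heat shock genes at -0.46 (adjusted p = 0.132, 9.1e-04 with the pairs as blocks, and 0.659 with blocks and an estimated correlation). The interferon response, a target of the poly(I)poly(C) that both genotypes received, was at -0.05 (adjusted p = 0.732), adhesion and niche retention at -0.10 (adjusted p = 0.355), chromatin repressors at -0.04 with a mean of 0.02 (adjusted p = 0.987) and ribosomal protein genes at -0.03 (adjusted p = 0.609). The test pointed upward for granule genes and mature granulocyte markers and downward for chromatin repressors, where median and mean differ in sign.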

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

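Chosen only after the results were seen were the tests of swaps within littermate pairs, of the normalization, of RNA quality for the 20 genes, of the Cre transgene, of granulocyte and monocyte progenitors and of a single aberrant pair, and the test of myeloid progenitors of every kind was made stricter after its value was seen.

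The knockout effects on T and NK, granulocyte, mitosis, erythroid and mast cell genes differed between populations by camera with the preset correlation, but no list passed with an estimated correlation, where the lowest adjusted p was 0.0700. T and NK cell markers rose less in myeloid progenitors than in LT-HSCs (-0.86, camera adjusted p = 3.82e-05) and less in MPPs than in LT-HSCs (-0.62, adjusted p = 0.00150). Mature granulocyte markers had a lower knockout effect in myeloid progenitors than in LT-HSCs (-1.10, adjusted p = 0.0156). Mitosis genes had a higher effect in myeloid progenitors (0.24, adjusted p = 0.00944) and in MPPs (0.51, adjusted p = 1.23e-07) than in LT-HSCs, and a lower one in myeloid progenitors than in MPPs (-0.32, adjusted p = 7.87e-05). Erythroid markers had a higher effect in MPPs than in LT-HSCs (0.29, adjusted p = 0.0237) and a lower one in myeloid progenitors than in MPPs (-0.47, adjusted p = 1.14e-09), and mast cell markers a lower one in myeloid progenitors than in MPPs (-1.13, adjusted p = 1.23e-07). With the pairs as blocks 9 further differences passed, with an adjusted p of 0.0129 to 0.0498. They were those of mast cell markers in myeloid progenitors (-0.42) and MPPs (0.68) and of mature granulocyte (-0.55) and B cell markers (0.59) in MPPs, all against LT-HSCs, and those of germline (0.34), lymphoid priming (0.31), granule (-0.11), replication (-0.12) and interferon genes (0.21) in myeloid progenitors against MPPs, none of which passed with an estimated correlation (adjusted p of 0.898 and more). The pairs of a population were uneven for some lists: mature granulocyte markers were at -0.52 and 1.68 and erythroid markers at 0.94 and -0.08 in the LT-HSC pairs, against 0.71 and 0.83 for erythroid markers in the MPP pairs, and mitosis genes were at 0.49 and -0.04 in the MPP pairs.

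Probe sets without a single gene symbol were used in no comparison of named genes. Of 1351 such probe sets past the filter 25 rose on average over the 3 populations, and 20 of those were higher on every knockout array than on any control array. The 3 with the largest differences were at 5.16, 4.97 and 4.66, with control signals at background, so that the pseudocount sets these sizes. Which transcripts they measure was not worked out here.

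The rise of 20 genes on average, with Tex19.1, Trap1a, Tex19.2 and Rhox5 at its head, was weighed against the processing, RNA quality and the transgene. In the values as deposited the median rise of the 20 genes was 2.19 against 2.25 after normalization, and 19 of the 20 passed, which argues against the normalization made here as the cause. With the Gapdh 3'/5' ratio as a covariate 20 of 20 passed with a median of 2.34. This argues against RNA quality, as that ratio measures it, as the whole cause. The Actb 3'/5' ratio did not follow that of Gapdh and was not used as a covariate. The transgene stays open: 0 arrays came from mice with Cre and intact Dnmt1, so an effect of Cre cannot be told apart from the loss of Dnmt1. The loss of Dnmt1 itself, which the design names, remains as the biological explanation and may account for the rise.

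Other splits of the arrays were counted for the 20 genes. Of 100 splits within populations 11 gave as many genes, the real one included, with up to 1042 in another, so these do not exclude chance. The 10 others parted 1 to 3 of the 7 littermate pairs, and the one with 1042 genes parted 1, which points to a structure of the arrays by pair. Of the 25 splits that parted all 7 pairs, the others gave 0 genes at most. Those 25 are among the 64 swaps within pairs and are no separate test. Of the 64 swaps 1 gave 20 genes, the real one, with 0 as the highest other. These swaps were chosen after the result, treat the 7 pairs as independent and can reach no share below 1 in 64. They argue against chance but do not exclude it.

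The same was done for the other counts. For the 8 genes of myeloid progenitors 1 of 10 splits gave as many, with 0 as the highest other, and 10 splits are too few for a share under 0.05. For the 8 list shifts on average 27 of 100 splits gave as many, with 13 as the highest other, so chance is not excluded there. Of 64 swaps within pairs 3 gave as many list shifts, with 8 as the highest other, a share under 0.05 in a test chosen after the result. Since 2 other swaps reached the same 8, this and the 100 splits together leave chance open for the list shifts. The lowest exact adjusted p over the 64 swaps was 0.195, for germline, lymphoid priming, T and NK and p53 genes among others, and 1 swap in 64 is the smallest share a list can reach. For the 4 list shifts of myeloid progenitors 5 of 10 splits gave as many, with 8 as the highest other. The real count was thus not unusual among the splits, and chance is not excluded there.

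Erythroid markers such as Car1, Ermap and Epor were higher in knockout MPPs, with a median of 0.69. A single aberrant pair is argued against, since the lower of the 2 pair medians was 0.71. Myeloid progenitors inside the sorted MPPs may have raised them: genes higher in control myeloid progenitors than in control LT-HSCs, 323 with the listed genes left out, had a median of -0.13 in knockout MPPs (camera p = 0.40 with an estimated correlation), which decides nothing. Granule genes, which granulocyte and monocyte progenitors would bring, had a median of 0.0244 with 9 of 16 positive. Their MPP pairs were at 0.37 and -0.25, so this does not decide it either. The Sca-1 gate of the sort is meant to remove myeloid progenitors, but how well it did so was not tested here. A change inside the MPPs and a shift towards erythroid progenitors among the sorted cells both stay open.

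T and NK cell markers such as Il2rb, Thy1 and Eomes were higher in knockout LT-HSCs, with a median of 0.66. RNA quality, as the Gapdh 3'/5' ratio measures it, is argued against as the whole cause. With that ratio as a covariate the median was 0.67 (camera p = 9.50e-04 with an estimated correlation). T or NK cells among the sorted cells may have raised them, since 15 further genes of such cells, listed before the test, had a median of 0.44 with 13 positive (camera p = 0.0155 with an estimated correlation). They ran from Gimap6 at -0.76 to Xcl1 at 1.36, the latter mostly from pair 2, and Ccl5, Ms4a4b and Gimap6 were already at 447.51 and 477.94, 253.1 and 241.39, and 484.37 and 363.77 on the control arrays, levels that would hide a small share of such cells. Lineage depletion and the Kit and Sca-1 gates are meant to remove such cells. Control LT-HSC arrays nevertheless carried more B cell marker signal than control MPPs (median 2.59), so complete removal cannot be assumed. Expression by the stem cells themselves was not tested, so it and T or NK cells among the sorted cells both stay open.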

How the results depend on the processing

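Alternatives added after the data were seen were those without both arrays of pair 1 of a population and the one with the Gapdh 3'/5' ratio as a covariate. All others were fixed in advance.

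Among the named genes, 2010 results of single genes kept their direction and their side of the threshold across the alternatives, 147 were weaker, 27 stronger and 50 reversed. Of the results of gene lists 371 kept both, 112 were weaker and 5 reversed. Of the counts 175 stayed within 1.5 times and 66 moved. Where no construction of the alternative shows it, the cause was not tested.

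The replicate block by littermate pairs gave 20 genes in LT-HSCs, 13 in MPPs, 13 in myeloid progenitors and 69 on average, and it also changed calls of single genes and lists, given with the results and with the differences between populations; the cause was not tested. A block by the number shared over populations left 4, 4, 7 and 19.

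The values as deposited gave 3 genes in MPPs and -0.0129 for Uhrf1 in LT-HSCs, and median centring gave -8.86e-04 for Uhrf1 there. No filter gave 3 genes in MPPs, the filter at the 60th percentile 3 in LT-HSCs and a median of -0.0606 for the imprinted list in MPPs, and eBayes without a trend 2 in MPPs. Pseudocounts of 1 and 64 put Tex19.1 on average at 6.89 and 3.42. Pseudocount 64 gave 1 gene in MPPs, 0 in myeloid progenitors and 3 between control myeloid progenitors and MPPs, which follows from its damping of dim genes. The mean over a gene's probe sets gave 3 genes in MPPs, 24 between control myeloid progenitors and MPPs, 0.14 for Dnmt3a in LT-HSCs and 0.10 for Dnmt3b in MPPs. All probe sets singly gave 12 in LT-HSCs, 22 in myeloid progenitors and 54 on average, counting probe sets and not genes. For the others the cause was not tested.

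Array weights gave 0 genes in LT-HSCs, 0 in MPPs, 15 in myeloid progenitors and 8 on average, 38 and 95 between control LT-HSCs or myeloid progenitors and control MPPs, and -0.12 for Xist in myeloid progenitors and -0.0673 on average; the cause was not tested. With only the arrays compared, which leaves fewer arrays to estimate the spread, the counts were 1 in LT-HSCs, 0 in MPPs, 2 in myeloid progenitors, and 34 and 13 for the control populations. Of the 24 list shifts 3 passed with an estimated correlation and 3 with fry, and with an estimated correlation and the pairs as blocks the lowest adjusted p was 0.265.

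Without both arrays of LT-HSC pair 1 there were 0 genes in LT-HSCs and 120 between control LT-HSCs and MPPs, Xist was at -0.10 in LT-HSCs and -0.0604 on average, Meis1 at 0.10 between the controls and the erythroid list at -0.0818 in LT-HSCs. Without MPP pair 1 there were 0 genes in MPPs, 11 on average, 86 and 0 between the control populations, Dnmt3b was at 0.14 and the mitosis list at -0.0368 in MPPs, and Il7r at 0.37 between control myeloid progenitors and MPPs. Without myeloid progenitor pair 1 there was 1 gene between control myeloid progenitors and MPPs, and Xist was at -0.0237 in myeloid progenitors and -0.0363 on average. With the Gapdh 3'/5' ratio as a covariate Cxcr4 and Mki67 were at 0.0445 and 0.0610 in myeloid progenitors, Mki67 at 0.0460 and Xist at -0.0436 on average, with 13 genes between control myeloid progenitors and MPPs. Beyond fewer arrays, the cause was not tested.

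Leaving out each array in turn, an arm left with 1 array is assumed to vary like the other groups. The counts ran from 2 to 77 in LT-HSCs, 0 to 2 in MPPs, 1 to 13 in myeloid progenitors, 12 to 59 on average, 78 to 422 between control LT-HSCs and MPPs and 0 to 188 between control myeloid progenitors and MPPs. The interaction counts ran from 0 to 4 for MPPs against LT-HSCs, 0 to 1 for myeloid progenitors against LT-HSCs and 0 to 1 for myeloid progenitors against MPPs.

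Genes and lists that changed sign when an array was left out had these ranges. In LT-HSCs they were -1.12 to 0.26 for Cxcr4, -0.36 to 0.24 for Dnmt3a, -0.56 to 0.11 for Mki67, -0.48 to 0.56 for Uhrf1, -0.27 to 0.56 for Xist and -0.18 to 1.08 for the erythroid list. In MPPs they were -0.49 to 0.00997 for Cxcr4, -0.79 to 0.10 for Dnmt3a, -0.52 to 0.45 for Dnmt3b, -0.49 to 0.0359 for Xist, -1.37 to 0.14 for the lymphoid list and -0.0554 to 0.54 for the mitosis list. In myeloid progenitors they were -0.53 to 0.34 for Cxcr4, -0.0440 to 0.26 for Dnmt3b, -0.22 to 0.0754 for Mki67 and -0.17 to 0.33 for Xist. On average they were -0.14 to 0.0855 for Mki67, -0.0411 to 0.30 for Uhrf1, -0.12 to 0.16 for Xist and -0.0119 to 0.25 for the median of the p53 list. Between the controls Meis1 ran from -0.86 to 0.10 and Il7r, in myeloid progenitors against MPPs, from -1.05 to 0.37. The cause was not tested.

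Signal over background limits the dim genes, since 31.1% to 37.4% of an array's values were below 16.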

Other observations

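The relation between Dnmt1 and the rise of the 20 genes was first tested as fixed before its result was seen, its repeat with 1 probe set was chosen after that result, and the genes in the next paragraph were chosen after their values were seen.

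Among the 20 genes that rose on average were 6 not named so far. Car3, a carbonic anhydrase of muscle and fat, rose by 1.21, the MHC class I gene H2-Bl by 1.21, the cell polarity gene Pard6b by 1.15, 4930550L24Rik by 1.15, Gm6958 by 1.04 and the prefoldin subunit gene Pfdn1 by 0.96, all with a limma adjusted p under the threshold and all higher in 7 of 7 littermate pairs. The probe sets used for Gm6958 and Pard6b are of the _x_ and _s_ kind and may also bind other transcripts. Other probe sets were at 1.75 for Gm6958, 1.04 for Pard6b and 0.42 for Car3 on average.

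The 20 genes rose by different amounts in the 7 pairs, from a mean of 1.57 in myeloid progenitor pair 1 to 3.05 in myeloid progenitor pair 2. A candidate explanation is Dnmt1 that was not deleted in part of the cells, which would leave a smaller rise where the Dnmt1 signal fell less. With the mean of both Dnmt1 probe sets, the measure tested first, the 7 pairs had a Pearson r of -0.78 (exact permutation p = 0.0522) and a Spearman rho of -0.75 (exact permutation p = 0.0663), and r was -0.44 without the 2 pairs farthest from the median. With the 1 probe set that stands for Dnmt1 in the comparisons, r was -0.92 (exact permutation p = 0.00516), rho -0.93 (exact permutation p = 0.00675), and r was -0.81 without the 2 farthest pairs. These 2 relations were the only ones computed, and since the call depends on the probe set, the hypothesis may hold but stays open.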
